A study of Mus musculus with 4 samples.

How the data were processed

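Mouse E14Tg2a embryonic stem cells were profiled as unmodified cells (WT) and as a triple knockout of Tet1, Tet2 and Tet3 (TetTKO), made with CRISPR and a pool of guide RNAs. Each genotype had 1 whole-genome bisulfite library (WGBS) and 1 RNA-seq library, so there were 4 libraries and 1 per group. Per the labels' protocols, both lines were adapted to medium with 15% serum and 1000 units/ml of LIF for at least 17 days before harvest.

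For WGBS, per the labels' protocols, 1 microgram of DNA with 0.5% unmethylated lambda DNA was sheared to about 350 bp, ligated to methylated adaptors, converted with bisulfite, amplified with 5 PCR cycles and sequenced as read pairs of 110 bp. Trim Galore, Bismark 0.7.9, Bowtie, SAMtools and the mm9 build are named in the submitters' processing notes, which give no further settings. The deposited methylation files hold, for each CpG, the fraction of reads that were methylated and the counts of methylated and of all reads. Both files list the same 14323377 CpGs, with a coverage of at least 5 in each library, and the strands of a CpG appear merged, since no listed positions lie 1 base apart. Bisulfite sequencing reads 5-methylcytosine and 5-hydroxymethylcytosine alike. The lambda reads were not used here, so conversion was judged only from unmethylated mouse DNA.

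For RNA-seq, per the labels' protocols, total RNA was depleted of ribosomal RNA, made into directional libraries and sequenced as single 50 bp reads. TopHat2 2.0.2 and Cufflinks 2.0.2 on mm9 are named in the submitters' processing notes. The gene models are not given in the sources used here. The deposited expression files hold FPKM (fragments scaled by transcript length and by the mapped reads of the library) per gene, rounded to 2 decimals, with a gene symbol and a genomic interval but no strand. The read depth of these libraries is unknown, since low values do not step by whole reads after the rounding. FPKM gives no counting interval, and a count model was not applicable.

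Gene values of 1 symbol with several rows were summed, and 6 short RNA genes were left out of the counts of genes. The comparison was log2((TetTKO + 1)/(WT + 1)) with a pseudocount of 1 FPKM, which understates the change of genes with low values. Genes with at least 1 FPKM in either library were counted as 2-fold higher or lower by size alone. A gene that reached 1 FPKM in only 1 library could differ only in the direction of that library. For each of 22 gene lists, the median over members of at least 1 FPKM was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. That percentile describes these libraries and is not a p-value. No p-value across genes, CpGs or windows was computed, because none of these is a replicate.

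Methylation was averaged over CpGs of the autosomes and X, over fixed 1 kb windows with at least 5 CpGs, over 100 kb bins with at least 50 CpGs, and over gene intervals. Windows were counted when they differed by at least 30 percentage points. For means by WT methylation, the class of a window was set from its odd-numbered CpGs and the difference measured on the even-numbered ones, to limit regression to the mean. CpG-rich windows held more than 15 CpGs, the 90th percentile. Spreads of genome-wide means are SDs over chromosomes, which measure evenness along the genome and not error between cultures. Exact 95% binomial intervals of read shares were taken on read calls summed over CpGs. A read that covers several CpGs enters once per CpG, and PCR copies are not independent molecules. The intervals are therefore too narrow even for counting error. Because the files give no strand, promoters were not defined. Both ends of each gene were used, from 1000 bp outside to 500 bp inside the interval.

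The window rule was tested on simulated data at the real coverage. In the simulated TetTKO against WT WGBS comparison over 1223855 windows, 86.0% of 200 windows raised by 40 points were recovered. These windows were drawn from those under 50% methylated, with independent CpGs, so the recovery of losses is unknown. With independent CpGs and no difference, 171 windows gained and 138 lost 30 points. With CpGs under 100 bp apart drawn as fully concordant, a harsher setting, 14853 gained and 14184 lost. It is not a strict upper bound on counting noise, since CpGs further apart can share a fragment of about 350 bp. The simulated RNA comparison with 200 altered genes of at least 5 FPKM recovered 100% of 3-fold and of 6-fold shifts over 10649 and 10666 genes, and 1% of 1.5-fold shifts over 10671 genes. A simulated list of 20 genes shifted by 0.5 on the log2 scale had percentile 100, and the same list unshifted had 68.6. Both RNA simulations assumed a noise level that was not estimated from these data. They check the calculation and do not measure the error of these libraries.

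The comparisons, gene lists, size rules, most alternatives and the rule for naming genes were chosen before the data were examined. The rule named Tet1, Tet2 and Tet3, the 15 genes of at least 5 FPKM with the largest differences each way, up to 4 list members per direction that differed at least 2-fold (or the member with the largest difference), up to 8 of the most expressed members of the DNA methylation and pluripotency lists, list genes or gene ends that differed by at least 30 points, and the 5 windows of at least 20 CpGs with the largest gain and loss. Other genes named in the text were chosen after their values were seen. A gene that the rule named is not reported here. Alternatives that leave out chromosome 6 or CpGs with coverage over 50, or that use at least 20 CpGs per window, window parts 300 bp long, a coverage of at least 10 for window counts or random lists matched on gene span, were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.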

Results

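The data set addressed what loss of the Tet enzymes, which oxidise 5-methylcytosine, does to DNA methylation and gene expression in mouse embryonic stem cells. E14Tg2a is a male, HPRT-deficient line. Each genotype had 1 WGBS and 1 RNA-seq library, so no value below has a replicate check. The WT WGBS library held 132794183 CpG read calls over the listed CpGs and the TetTKO library 150132176, with median coverages of 8 and 10. FPKM of at least 1 was recorded for 10458 genes in the WT RNA library and 10740 in the TetTKO library. Across genes, log2(FPKM + 1) of the libraries had a Pearson correlation of 0.981, and genes are not independent replicates.

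Tet1 and Tet2 mRNA were lower in the TetTKO library, and Tet3 was near the floor in both. Tet1 (mm9 chromosome 10, 62267318 to 62342762) had 15.1 FPKM in WT and 4.36 in TetTKO, 3.45-fold lower. Tet2 (chromosome 3, 133126641 to 133207354) had 14.9 and 4.13 FPKM, 3.60-fold lower. Tet3 (chromosome 6, 83312368 to 83391672) had 0.32 and 0.27 FPKM, so its RNA carries no information on the genotype. A gene-level FPKM cannot show an indel. The Tet1 interval was also more methylated in TetTKO, at 62.2% against 47.9% over 784 CpGs, and held 9 of the 1 kb windows that gained at least 30 points. The Tet2 interval had 46.2% in WT and 49.4% in TetTKO, and Tet3 had 75.5% and 74.4%.

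Chromosome 6 stood apart between the libraries in WGBS coverage and in expression. WT coverage per CpG on chromosome 6 was 1.34 times that of the median autosome, whereas the other 18 autosomes lay between 0.986 and 1.02. In TetTKO, chromosome 6 stood at 0.982. The 309 chromosome 6 genes with at least 5 FPKM in both libraries had a median log2 fold change of -0.52, and 91.3% of them were lower in TetTKO. Medians of the other autosomes ran from -0.07 for chromosome 8 to 0.08 for chromosome 11. Chromosome 6 genes are marked as such below.

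**Figure D1:**
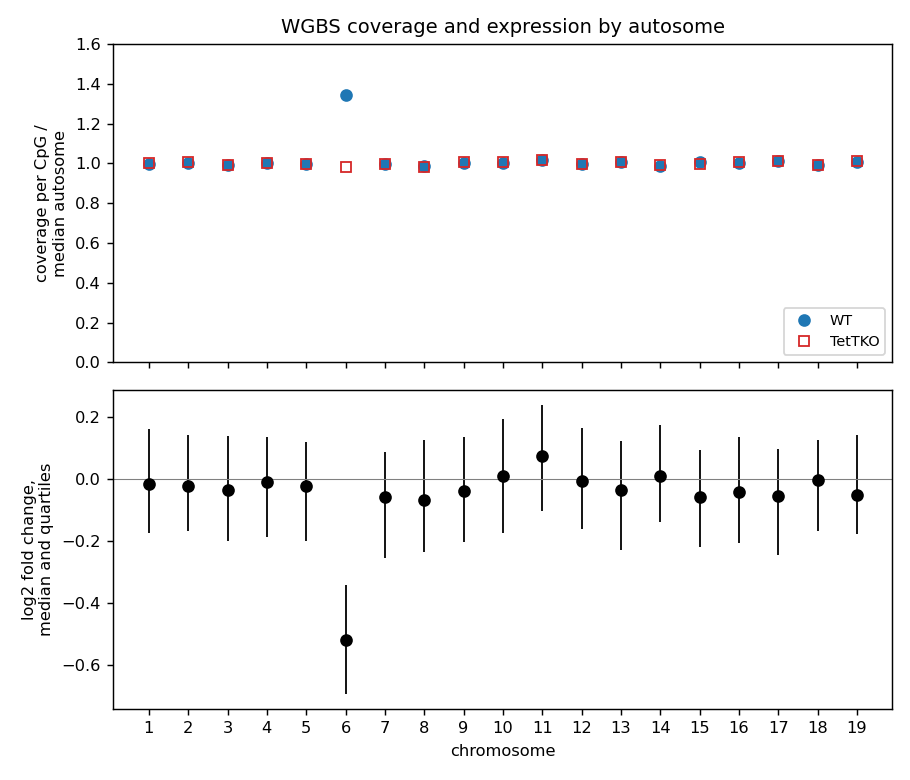
WGBS coverage per CpG relative to the median autosome (upper panel, WT filled, TetTKO open) and the log2 fold change of genes with at least 5 FPKM in both libraries (lower panel, points are medians and bars quartiles), by autosome. Chromosome 6 stands at 1.34 in WT and 0.982 in TetTKO, with a median log2 fold change of -0.52.

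Of 10978 genes, 194 were at least 2-fold higher in TetTKO and 93 at least 2-fold lower. The counts depended on the pseudocount, at 479 and 213 with 0.1 FPKM and 40 and 28 with 5 FPKM. Chromosome 6 held 28 of the 93 and 5 of the 194, against 4.67% of the genes counted. Without chromosome 6, 189 genes were higher and 65 lower. The 15 genes with the largest differences upward included members of the 2-cell-stage list, described below. Zfp951 (chromosome 5, 105242187 to 105289087) had 4.09 FPKM in WT and 31.2 in TetTKO. Stra8, the retinoic acid target needed for entry into meiosis (chromosome 6), had 1.89 and 16.7 FPKM, higher although its chromosome as a whole was lower. Gm7102, Gm5039, Dcdc2c, D17Ertd648e and Efhc2 were 4.42-fold to 8.57-fold higher. Downward, the macrophage metal transporter gene Slc11a1 (chromosome 1, 74421777 to 74432625) had 6.34 FPKM in WT and 0.34 in TetTKO, and Gm216, which lies beside it, had 5.89 and 0.50. Lrrc34 had 41.8 and 9.33 FPKM, Plac8 28.9 and 6.89, Pqlc1 24.1 and 6.08, 2410004A20Rik 70.5 and 21.6, and Nkx6-2 8.18 and 2.24. The chromosome 6 genes Emp1 (30.9 and 5.03 FPKM), 1190002F15Rik (10.2 and 1.11), Trh (839 and 281), Cd9 (190.5 and 63.4) and Mitf (6.03 and 1.47) were lower by more than their chromosome's median. The Y-linked helicase gene Ddx3y had 26.2 FPKM in WT and 6.64 in TetTKO, and Eif2s3y and Uty were 2.60-fold and 2.73-fold lower, whereas the Y-linked Ube1y1 was higher, at 1.68 and 2.95 FPKM. These last 3 genes were named after their values were seen.

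**Figure D2:**
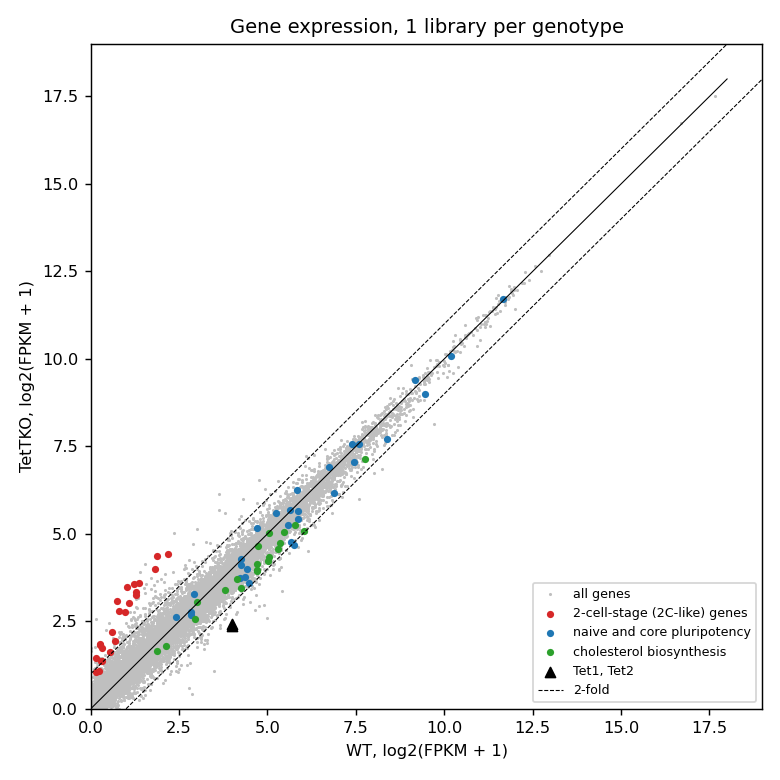
Each point is a gene, placed by log2(FPKM + 1) in the WT (horizontal) and TetTKO (vertical) library; the dashed lines mark 2-fold. The 2-cell-stage genes (red) had a median log2 fold change of 1.79, pluripotency genes (blue) -0.15 and cholesterol biosynthesis genes (green) -0.54.

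Genes of the 2-cell embryo were higher as a group. Of 23 measured members of the list, 21 were at least 2-fold higher and none was lower, with a median log2 fold change of 1.79, at percentile 100 of the random lists. Zscan4d, of a family of telomere-associated zinc finger genes expressed at zygotic genome activation, had 1.35 FPKM in WT and 10.9 in TetTKO. Zscan4a had 1.6 and 11.1 FPKM and Zscan4f 1.43 and 9.20. The 6 listed Zscan4 copies, whose near-identical sequences make the split of reads between them uncertain, summed to 5.93 and 40.7 FPKM, 6.86-fold higher. Other members of the list, Gm12794 (1.02 and 10.2 FPKM), Gm8994 (2.65 and 19.8, chromosome 6), Dub1a (0.66 and 7.50), Gm2022 (3.56 and 20.5) and Gm8300 (2.51 and 15.1), were also higher. WT values in the list were at most 3.56 FPKM. Members under 1 FPKM in WT, Dub1a among them, were measured only through TetTKO and could only be higher. Those with at least 1 FPKM in WT were all at least 2-fold higher. The list median depended on the pseudocount, at 2.58 with 0.1 FPKM and 0.86 with 5 FPKM. It was 1.08 with all listed genes kept.

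Germline genes whose promoters are methylated in somatic cells were higher too, by less. Their list had a median of 0.49 (percentile 100), or 0.27 with a pseudocount of 5 FPKM, with 5 of 26 members at least 2-fold higher and none at least 2-fold lower. Sycp1, a synaptonemal complex protein, had 1.17 FPKM in WT and 5.87 in TetTKO. Taf7l had 1.41 and 4.45, the piRNA pathway gene Mael 9.96 and 22.4, and Syce3 1.75 and 4.70.

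Markers of the formative and primed epiblast and of primitive endoderm were higher in TetTKO, while the pluripotency list stood slightly lower. The formative and primed list had a median of 0.71 (percentile 100), or 0.39 with a pseudocount of 5 FPKM, and 18 of 19 members were higher, 5 of them at least 2-fold. Otx2, a driver of the exit from naive pluripotency, had 3.98 FPKM in WT and 13.97 in TetTKO, Wnt8a 1.47 and 6.34, and Pou3f1 2.39 and 7.32. Primitive endoderm genes had a median of 0.85 (percentile 100), from 0.44 to 1.34 with pseudocounts of 5 and 0.1 FPKM, with all 14 measured members higher and 4 at least 2-fold. These were the basement membrane collagens Col4a1 (6.44 and 25.4 FPKM) and Col4a2 (2.5 and 8.34), the receptor Pdgfra (0.73 and 3.16) and Cubn (0.58 and 2.40). On both lists, members under 1 FPKM in WT, Pdgfra and Cubn among them, were measured only through TetTKO and could only be higher. The primitive endoderm members with at least 1 FPKM in WT were all higher too. The naive and core pluripotency list had a median of -0.15 (percentile 3.56), which was -0.08 without its 3 chromosome 6 members. Its most expressed members stayed within 2-fold. Dppa5a had 3211 and 3344 FPKM, Pou5f1 1178 and 1092, Tdgf1 573 and 679, Sox2 192 and 187, Fbxo15 167 and 190, Zfp42 698 and 513, Tdh 330.2 and 208, and Dppa4 172 and 133. Tcl1 alone was at least 2-fold lower, at 52.5 and 24.8 FPKM. Nanog, on chromosome 6, had 116 and 71.0 FPKM. Nanog was named after its values were seen.

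Other lineage lists rested on few expressed members. Neuroectoderm genes had a median of 0.53 over 8 members (percentile 99.9), with Nes at 2.59 FPKM in WT and 8.08 in TetTKO. That median was 0.03 when all listed genes were kept. Trophoblast genes had 0.39 over 10 members (percentile 98.95), Gcm1 having 0.15 and 1.41 FPKM, and 0.10 with all listed genes kept. Primitive streak and mesoderm genes had 3 measured members and a median of 0.50 (percentile 93.6), or 0.046 with all listed genes kept, and Bmp4 went the other way, with 23.5 FPKM in WT and 10.04 in TetTKO. No Hox gene reached 1 FPKM in either library. Of the fibroblast and feeder markers, the smooth muscle genes Acta2 (1.86 and 9.84 FPKM) and Tagln (8.59 and 26.4) were higher, but the list median was 0.13 (percentile 83.9).

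Among DNA methylation genes, the de novo methyltransferase gene Dnmt3b alone passed the 2-fold rule. Dnmt3b, also on the formative and primed list, had 66.9 FPKM in WT and 149 in TetTKO, 2.23-fold higher. Dnmt3a had 14.7 and 30.3 FPKM, a log2 fold change of 0.99, which falls short of the rule only because of the pseudocount, its plain ratio being 2.06. Uhrf1, which brings Dnmt1 to replicating DNA, had 109 and 71.8 FPKM, while Dnmt1 had 59.8 and 65.8 and Dnmt3l 291 and 304. Mbd3 had 41.5 and 31.0 FPKM. On chromosome 6, Gadd45a had 36.6 and 44.8 FPKM and Mbd4 10.04 and 5.82. The whole list had a median of 0.00019 (percentile 57.7).

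The cholesterol biosynthesis list was the lowest of all, with a median of -0.54 (percentile 0). Of its 20 measured members 19 were lower and none by 2-fold, and no member lies on chromosome 6. The largest difference was that of Sc4mol, a sterol demethylase gene, with 65.1 FPKM in WT and 32.9 in TetTKO. Genes of the p53 response had a median of 0.31 (percentile 100), with the pro-apoptotic Pmaip1 (5.33 and 15.3 FPKM), Perp (17.3 and 42.0) and Plk2 (29.99 and 62.0) at least 2-fold higher. Cdkn1a, the usual p53 target of cell cycle arrest, was not among them, at 3.81 and 2.23 FPKM. It was named after its values were seen.

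Imprinted genes had a median of 0.10 (percentile 93.5) with members going both ways. H19 (chromosome 7, 149761437 to 149764051) had 1.43 FPKM in WT and 7.80 in TetTKO, Grb10 16.7 and 5.78, and Slc22a18 1.66 and 0.28. Nodal and Lefty signalling genes had a median of 0.20 (percentile 98.5), or 0.094 with all listed genes kept, none differing 2-fold, and Smad3 differed most, at 1.65 and 2.88 FPKM. Wnt/beta-catenin response genes had 0.20 (percentile 86.7), with Ccnd2, on chromosome 6, at 5.57 and 1.37 FPKM. MAPK/FGF response genes had 0.01 (percentile 58.1), with the phosphatase gene Dusp4 at 6.25 and 14.9 FPKM. Glycolysis genes had 0.02 (percentile 84.4), with Pfkp at 112 and 47.0 FPKM. Telomere maintenance genes had -0.01 (percentile 63.2), Atrx having 18.17 and 27.9 FPKM, and interferon response genes had -0.02 (percentile 40.2), Oas1a having 1.56 and 3.90. Housekeeping genes had 0.02 (percentile 77.1). Replication-dependent histones and other RNAs without poly(A) tails had -0.20 (percentile 0.81), Hist1h1b having 1216 and 776 FPKM.

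**Figure D3:**
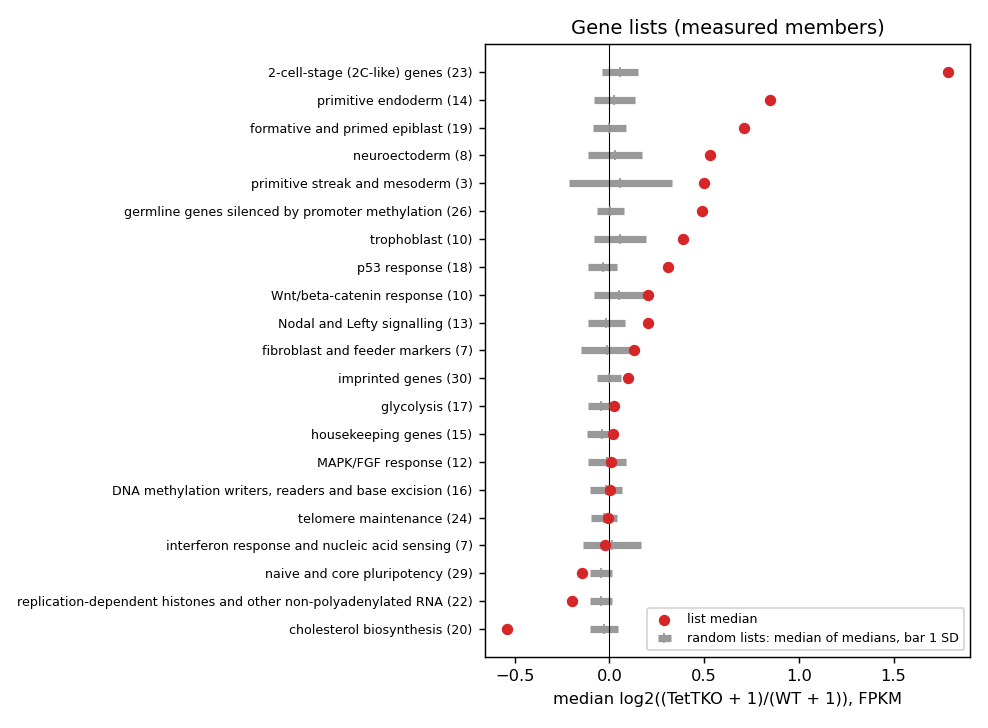
Red points are the median log2 fold change of each gene list, with the number of measured members in parentheses, and grey bars the median of 10000 matched random lists with 1 SD each way. The 2-cell-stage list stands at 1.79 and cholesterol biosynthesis at -0.54.

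Methylation of the genome was lower in TetTKO on average. Over 14321696 CpGs of the autosomes and X, the mean was 69.5% in WT and 65.0% in TetTKO, a difference of -4.45 percentage points with an SD over chromosomes of 0.871. Autosomes ranged from -5.35 to -3.04 points and the X chromosome stood at -7.13. Pooled over all CpG read calls the shares were 69.3% (exact 95% interval 69.33 to 69.35) and 64.8% (64.78 to 64.80). Windows over 80% methylated made up 49.7% of 1223855 windows of 1 kb in WT and 19.9% in TetTKO, and 72.1% of windows were lower in TetTKO.

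The direction depended on the starting level and on CpG density. CpG-rich windows of 10 to 50% in WT were higher in TetTKO, at 41.5% against 28.8%, a difference of 12.6 points (SD over chromosomes 0.988) over 21648 windows. CpG-rich windows under 10% had 2.75% in WT and 6.40% in TetTKO. Windows over 80% were lower, with differences of -8.31 points where CpG-poor (577547 windows) and -6.15 where CpG-rich. Between 50 and 80% the differences were -4.86 points where CpG-poor and 0.686 where CpG-rich. CpG-poor windows showed 10.01 points under 10% and 7.91 points from 10 to 50%, but these depended on how classes were set. With the class taken from the first 300 bp and the difference from the last 300 bp of a window they were 1.81 and -1.34 points, and the CpG-rich value of 12.6 was 5.63. With classes set from TetTKO, CpG-rich windows under 10% differed by 1.48 points where the main value is 3.65, windows over 80% differed by -4.15 points where CpG-poor and -1.56 where CpG-rich, and CpG-rich windows of 50 to 80% by -0.141. Over all settings tried, CpG-rich windows under 10% ran from 1.48 to 5.06 points and CpG-poor windows of 50 to 80% from -6.73 to -2.81.

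**Figure D4:**
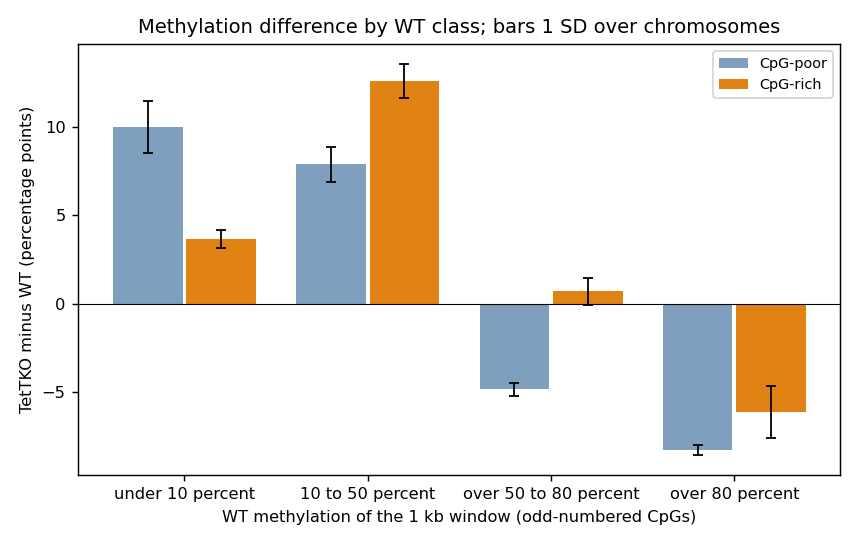
Bars give the mean TetTKO minus WT methylation of 1 kb windows in percentage points, by WT methylation class and CpG density, with error bars of 1 SD over chromosomes. CpG-rich windows of 10 to 50% stood at 12.6 points and CpG-poor windows over 80% at -8.31.

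At the scale of 100 kb, bins with few listed CpGs differed more than those with many. Listing required coverage in both libraries, so this ranking reflects coverage as well as CpG density. Chromosome X listed 160303 CpGs, at 0.735 of the median autosome's coverage in WT and 0.692 in TetTKO. Its share of the lowest decile was not determined. The decile of bins with the fewest CpGs had 73.1% in WT and 64.8% in TetTKO, a difference of -8.28 points, and 97.8% of its bins were lower. The next 2 deciles stood at -8.99 and -8.71 points. The densest decile had 57.8% and 57.4%, a difference of -0.353, or -1.19 in 1 Mb bins. Outside windows under 50% in WT, the densest decile differed by -4.78 points. The last 2 Mb of the 19 autosomes did not stand apart from the rest, with an excess of 0.0837 points against an SD over chromosomes of 2.53.

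**Figure D5:**
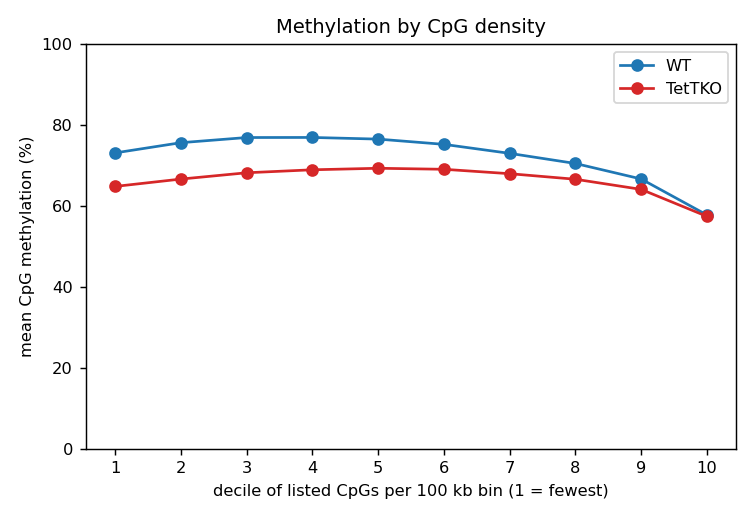
Mean CpG methylation of 100 kb bins in WT (blue) and TetTKO (red), by decile of CpGs listed per bin. TetTKO minus WT is -8.28 points in decile 1, and the lines almost meet in decile 10, at 57.8% and 57.4%.

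Counts of 1 kb windows were 8197 with at least 30 points more methylation in TetTKO and 7812 with at least 30 points less. Both lie below the counts simulated with concordant CpGs and no difference, 14853 and 14184 over all windows. They lie above the counts simulated with independent CpGs, 171 and 138. The concordant simulation exceeds the data both ways, so it does not give the noise level of these libraries, which was not measured. These counts alone therefore cannot set regional differences apart from noise. Centred on the median window difference, 17513 windows gained and 1617 lost. Windows of at least 20 CpGs were one-sided, with 792 higher and 18 lower of 51982. For these the concordant simulation gave 787 and 780, and the simulation with independent CpGs 0 and 0. The 18 lower windows lie far below 780, so 787 is no measure of the noise among the gains. Gaining windows averaged 27.5% in WT and 64.0% in TetTKO. When windows were picked on a gain in their first 300 bp, their last 300 bp differed by 7.02 points, against -2.55 for all windows. Windows picked on a loss in the same way differed by -5.23 points.

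Read numbers of windows count a read once for each CpG it covers. Among windows of at least 20 CpGs, the largest gains were as follows. The window at chromosome 14, 104128000 to 104128999, 23984 bp from Slain1, had 14.04% of 228 reads methylated in WT (exact 95% interval 9.80 to 19.2) and 77.4% of 190 in TetTKO (70.8 to 83.1). A window within Nr4a2, an orphan nuclear receptor gene (chromosome 2, 56962000 to 56962999), had 22.7% of 203 reads and 80.4% of 199. One within Bach1 (chromosome 16, 87721000 to 87721999) had 19.7% of 223 and 75.8% of 227. Windows within 1700106N22Rik (chromosome 17, 85656000 to 85656999) and 152 bp from Irgm1 (chromosome 11, 48685000 to 48685999) had 7.07% and 20.1% in WT and 68.0% and 78.6% in TetTKO. The largest losses were within Fgf14 (chromosome 14, 124429000 to 124429999), with 83.2% of 179 reads in WT and 31.4% of 172 in TetTKO, 30827 bp from Vpreb2 (chromosome 16, 18012000 to 18012999; 76.2% and 33.1%), in the Pcdha protocadherin cluster (chromosome 18, 37127000 to 37127999; 58.7% and 15.2%), 13869 bp from Fbxl20 (chromosome 11, 97929000 to 97929999; 49.4% and 8.93%) and within Tmem40 (chromosome 6, 115680000 to 115680999; 52.9% and 13.9%). Whether these windows lie in exons or introns was not determined, since no annotation of that build was used here.

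Methylation of whole gene intervals followed the genome. Over 21330 genes the median difference was -3.01 points, with 15 genes at least 30 points higher and 14 at least 30 points lower. Genes of the fixed lists among these were Rhox6, with 26.9% in WT and 74.7% in TetTKO over 7 CpGs, and the RNA genes Rmrp (0% and 64.9%) and Rpph1 (0% and 51.5%), whose TetTKO reads are described among the additional observations. Of 39190 gene ends, 210 were at least 30 points higher and 83 at least 30 points lower. Among genes of the fixed lists, the 14 of the MAPK/FGF response held 3 of the ends that were higher. Whether this exceeds the share over all gene ends was not tested. The lower-coordinate end of Etv4 had 17.5% in WT and 59.0% in TetTKO over 16 CpGs, the higher-coordinate end of Myc 20.8% and 59.3%, Tal1 12.4% and 46.8%, Bmp4 41.7% and 75.1% over 6 CpGs, Klf4 18.1% and 50.0%, Zic2 12.9% and 45.3%, Hoxd9 12.6% and 43.4%, Tlr3 11.2% and 43.8%, and Spry4 24.5% and 55.2%. The long non-coding RNA gene Neat1 had 13.9% and 58.6% at an end with 9 CpGs. Spry1, also of the MAPK/FGF response list, was lower, at 88.0% and 49.2% over 7 CpGs. Of 11839 ends under 10% in WT, 41 exceeded 30% in TetTKO.

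Genes at least 2-fold lower in TetTKO held windows of gained methylation more often than the rest, while genes with such windows had a median fold change near 0. Across 10932 genes, which are not independent replicates, Spearman's rho between the interval difference and the log2 fold change was -0.17. A gaining window was held by 42.2% of the lower genes (38 of 90), by 10.1% of genes at least 2-fold higher (19 of 188) and by 18.6% of the rest. Losing windows occurred in 4.44%, 13.8% and 9.76% of these groups. The 2036 genes with a gaining window had a median log2 fold change of -0.01, at percentile 6.85 of expression-matched lists and at percentile 0 of lists matched also on gene span. Under a rule of 20 points the percentile was 38.8, and without chromosome 6 the median turned to 0.0032, at percentile 19.3. The 1070 genes with a losing window had a median of 0.08, at percentile 100, where matched lists had a median of 0.0015. Lists matched also on gene span had a median of 0.05, which put the losing genes at percentile 99.9. Under a rule of 20 points their median was 0.032. Without chromosome 6, 25 lower and 19 higher genes had a gaining window, out of far fewer lower than higher genes.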

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

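All tests on chromosome 6 and the tests of shared reads and of low genes on the 2-cell-stage list were chosen after the result was seen. The tests of bisulfite conversion were set beforehand.

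Read coverage, which the comparisons did not use, stood out for chromosome 6 in the WT library, at 1.34 times the median autosome. Its 30 bins of 5 Mb ran from 1.19 to 1.42, above each of the 468 bins of other autosomes (0.892 to 1.16), so an extra copy of the whole chromosome in part or all of the WT culture is a candidate explanation for the lower expression of its genes in TetTKO. A missing copy in TetTKO is argued against by a TetTKO coverage of 0.982, and a gain of methylation along the chromosome by its difference of -4.95 points, inside the range of the other autosomes (-5.35 to -3.04). CpGs were listed only at a coverage of 5 or more, which compresses the ratio, so the share of cells with an extra copy cannot be read from it. Other explanations of the chromosome 6 result tied to Tet loss were not tested.

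The lower methylation of highly methylated DNA in TetTKO is not what incomplete conversion of the WT library would give. Windows under 2% in TetTKO had 1.48% in WT, against a mean loss of 4.45 points and a bound of 2.22 set beforehand. More conversion of methylated cytosines in the TetTKO library would scale highly methylated windows alike. The TetTKO over WT ratio was 0.885 in the decile with the fewest listed CpGs and 0.911 in that with the most. These ratios include chromosome X, whereas the SD is over autosomes. The gap of 0.0260 had the same sign in 19 of 19 autosomes. It was under 2 SDs over autosomes (0.0170), the bound set beforehand, so this explanation stays open. Loss of Tet activity, and any difference between clones or cultures, cannot be told apart with 1 library per genotype.

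For the 2-cell-stage genes, reads shared between near-identical copies are argued against by members taken as single-locus genes. Arg2, Tmem92, Sp110 and Zfp352 had TetTKO over WT ratios from 4.60 to 6.98. Their WT values were under 1 FPKM, however, so they counted as measured only through TetTKO. A general rise of low genes is argued against as well, since 3.32% of 3921 other genes under 5 FPKM in WT were at least 2-fold higher. A larger share of cells in a 2-cell-like state may explain the 21 higher members, but bulk RNA cannot separate it from a higher level in every cell.

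Coverage also stood out inside Rmrp, the RNA component of RNase MRP (chromosome 4, 43505657 to 43505931). In TetTKO it was 3.90 times that of its 500 bp flanks, against 0.917 in WT. Calls here count a read once for each CpG it covers. In TetTKO, 761 of 1128 calls were methylated inside and 0 of 258 in the flank on the higher-coordinate side. The flank on the other side was partly methylated in both libraries, at 25.4% in WT and 42.0% in TetTKO over 9 CpGs. Rpph1, the RNA of RNase P (chromosome 14, 51427122 to 51427446), had 42 of 78 TetTKO calls methylated inside and 0 of 267 in that flank. Its coverage in TetTKO was 0.876 times the flank. Neither gene had a methylated call in WT, of 263 over 26 CpGs and 60 over 10 CpGs, at mean coverages of 10.1 and 6. They had the highest FPKM in TetTKO among genes with an interval value, and the largest gains of any gene interval. The cause was not tested.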

How the results depend on the processing

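The main results kept their direction under most settings, and 127 of 200 alternatives moved a main value by less than 1 SD (over chromosomes or random lists) or, for counts, by less than 1.5 times. Some of the 127 were fixed in advance. Rescaling the libraries moved list medians by less than the smallest SD of random lists, 0.056. Lists with no measured member on chromosome 6 kept their value without that chromosome. The mean CpG difference stayed between -5.08 and -4.41 points in its 6 alternatives. For named genes, 200 of 237 recomputed values moved by less than 1.5-fold. Those from the rescaling, by a median log2 fold change of -0.04, could not have moved more, so that part of the 200 was fixed in advance. Their sign is no check, since neither a pseudocount nor the small rescaling used can turn a 2-fold difference. Settings without chromosome 6, with at least 20 CpGs, coverage of 10 for windows, 300 bp parts or span-matched lists were chosen after seeing the data. Using all CpGs listed in each library could not be run as another setting, since both list the same CpGs. No paired analysis was possible because each group has 1 library. Except where fewer genes, CpGs or windows entered, or the rule itself was stricter or looser, the cause was not tested.

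Genes at least 2-fold higher and lower numbered 479 and 213 with a pseudocount of 0.1 FPKM, 40 and 28 with 5 FPKM, and 18 and 5 under a 4-fold rule; 119 were higher with a filter of 5 FPKM. With 0.1 FPKM, list medians were 2.58 (2-cell-stage), 0.59 (germline), 0.58 (trophoblast), 1.34 (primitive endoderm) and 0.98 (mesoderm). With 5 FPKM they were 0.86, 0.27, 0.16, 0.44 and 0.16, with 0.39 for formative and primed and 0.19 for neuroectoderm. With no filter they were 1.08 (2-cell-stage), 0.36 (germline), 0.10 (trophoblast), 0.66 (primitive endoderm), 0.046 (mesoderm), 0.035 (neuroectoderm) and 0.094 (Nodal and Lefty). Without chromosome 6, the 2-cell-stage median was 1.69 and pluripotency -0.085. The median log2 fold change of genes over 5 FPKM in both libraries was -0.04, and rescaling it to 0 turned the sign of the telomere and interferon medians, which lie within that shift.

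Windows gaining and losing 30 points numbered 2002 and 4280 at 2 kb, 4588 and 348 with at least 10 CpGs, 792 and 18 with at least 20, and 2354 and 591 at a coverage of 10. At 500 bp 17054 gained. A rule of 20 points gave 29397 and 78461, and 40 points 1806 and 491. Centred on the median window difference, 17513 gained and 1617 lost, so the split between gain and loss depends on the centring.

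Classes set from TetTKO gave, in points, CpG-poor then CpG-rich, 2.11 and 1.48 under 10%, -1.32 and 9.02 from 10 to 50%, -6.73 and -0.141 to 80%, and -4.15 and -1.56 above. Set from the mean of both libraries they gave 4.25 and 2.08, 5.395 and 11.6, then -6.32 and -6.71 for CpG-poor windows to 80% and above. From the first and last 300 bp they gave 1.81 and 5.06, -1.34 and 5.63, -6.00 for CpG-poor to 80%, and -6.98 and -3.40 above. From all CpGs at once, CpG-poor windows gave 11.8 from 10 to 50%, -2.81 to 80% and -10.3 above. The CpG-poor class of 10 to 50% thus reversed under both the TetTKO classes and the 300 bp parts. The densest decile gave -1.19 in 1 Mb bins and -4.78 without windows under 50%.

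Genes with a gaining window had a median of 0.0032 without chromosome 6, and percentile 0 among span-matched lists. Genes with a losing window had 0.032 at 20 points and 0.10 with a pseudocount of 0.1 FPKM. Median coverages of 8 and 10 limit single windows of few CpGs, and values near 1 FPKM limit the 2-cell-stage and lineage genes.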

Other observations

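Ends of several imprinted genes were less methylated in TetTKO, below the size rule of 30 points. Of 14 imprinted gene ends of 20 to 80% in WT with at least 15 CpGs, some of them overlapping, 9 were lower and 5 higher, a choice made after their values were seen. The Plagl1 end had 62.4% in WT and 42.1% in TetTKO, the Peg3 end 44.8% and 24.8%, the Usp29 end, which overlaps it, 43.0% and 22.4%, and the Kcnq1ot1 end 41.4% and 22.4%. On chromosome 6, the Mest end had 77.6% and 50.7%, and the Nap1l5 end 57.2% and 40.2%. Among the other ends were Meg3 at 32.5% and 33.9%, Nnat at 37.7% and 38.7%, and Slc38a4 at 24.99% and 26.9%, and the Zim1 end was higher, at 20.3% and 33.8%. Mest RNA was higher in TetTKO, at 6.35 and 10.6 FPKM, as was Peg10, on chromosome 6, at 7.41 and 14.4, both against the direction of their chromosome. Peg3 RNA was 3.88 and 4.04 FPKM and Snrpn 56.2 and 85.9.

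The phosphofructokinase gene Pfkp had 112 FPKM in WT and 47.0 in TetTKO, whereas Pfkl had 97.4 and 170.2 and Pfkm 8.37 and 17.2, a plain ratio of 2.05 that misses the 2-fold rule only because of the pseudocount. Among naive pluripotency regulators off chromosome 6, Esrrb had 49.3 and 26.4 FPKM and Tfcp2l1 21.1 and 11.0, while Sall4 had 25.1 and 34.6. These genes were chosen after their values were seen. Hprt had 1.05 and 0.92 FPKM in this HPRT-deficient line. Of the Y-linked genes, Ddx3y, Eif2s3y and Uty were lower in TetTKO and Ube1y1 was higher, at 1.68 and 2.95 FPKM. Mean coverage of the 474 CpGs listed on chromosome Y below position 800000 was 6.30 in WT and 6.33 in TetTKO, near the listing minimum of 5. These values are not scaled to library depth. The median autosome had 8.86 in WT and 10.2 in TetTKO, and chromosome X 6.51 and 7.09. Near-equal raw values therefore do not show equal dosage of chromosome Y.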
